A study of Homo sapiens with 12 samples.

How the data were processed

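Ribosome footprints of HEK293 cells were measured in 3 conditions (log phase, 2 h without serum, 1 h without amino acids) and 2 pooled gradient fractions (monosome and polysome), with 2 libraries per group and 12 libraries in all. Per the labels, lysates held cycloheximide, footprints of 17 to 34 nt were kept, libraries were amplified with 14 PCR cycles and read for 75 nt. The processing notes list Bowtie 1.0 and hg38 without saying what each was used for. The series holds 1 table of 149028 ORFs. Its values per library are expected counts, which the authors deposited as the output of the ORF caller PRICE, named in the title of the file, and which divide footprints among the ORFs they could come from. The caller's p-value per ORF was also deposited by the authors, and it was used only to form a stricter set of ORFs with p under 1e-4.

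The ORFs overlap, so each codon was counted once. Coding types (CDS, Trunc and Variant) came first and higher totals next, which kept 124829 ORFs, 7031 of them coding, in 6375 genes. Expected counts of the kept coding ORFs were summed per gene and rounded to whole numbers. The table gives gene identifiers only. Names were taken from RefSeq by position where all coding ORFs of a gene lay inside 1 protein-coding gene, which named 5892 genes. Another 219 lay inside several genes and 264 inside none, and these keep their identifiers. DDIT3 and ASNS, stress response genes chosen in advance, have no tested coding ORF under their names. Many called ORFs are fragments, and the length given for a gene is that of its kept coding ORF with the highest count.

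Depth was 354507 to 1204002 footprints in the monosome libraries, of which 119947 to 346200 were coding, and 2477823 to 7683729 in the polysome libraries, of which 1493881 to 5313462 were coding. The common biological coefficient of variation was 0.433. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 4765. Counts were scaled by TMM and fitted with edgeR 4.0.16 quasi-likelihood models over 6 groups in R 4.3.3. There were 12 contrasts: monosome against polysome in each condition and over their mean, the 3 pairs of conditions within each fraction (log2 of the first over the second), and the change of the monosome over polysome ratio in each starvation against log phase. Tests were two-sided with Benjamini-Hochberg adjusted p under 0.05 per contrast. Counts of genes at an unadjusted p under 0.05 are also given, and chance alone would put a share of about 0.05 of tested genes there. The counts without a replicate term come from the model chosen before the data were examined, and the replicate block was 1 of the alternatives listed at that time. The letters A and B of the columns served as replicate numbers. No label ties a letter to a replicate number. The B minus A deviations correlated over genes between groups with r of 0.161 to 0.866, and of 0.770 to 0.866 between polysome groups. Giving the blocked values beside the others was decided after the data were seen.

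Of 24 gene lists fixed in advance, 20 had at least 5 tested members and were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. Members were also adjusted over the list alone. ORF classes were tested in the same way on all kept ORFs. Shares of footprints were compared by an exact stratified permutation of the fraction labels within condition, and, added after the data were seen, by swaps within the pairs of 1 condition and letter. Genes were named by a rule fixed in advance: up to 10 per direction by size of change among genes that passed, did not overlap between groups and averaged at least 50 footprints per library in the higher group, the 4 members of each list with the smallest p, and a few genes chosen in advance. Genes with 3 or fewer footprints in a group get no size. The share of the mitochondrial chromosome and length-matched draws were added after the data were seen.

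Alternatives were DESeq2 1.42.0, RLE and library-size scaling, no filter and a filter of 50 counts in 2 libraries, the compared groups alone, CDS-type ORFs alone, 3 forms of replicate block, thinning to 119885 footprints per library, and leaving out each library. The models were tested on simulated data with 200 changed of 4765 genes and a letter effect that was the same in both fractions. Dispersions came from the blocked fit, so the setting is the one the block assumes. In the data the B minus A deviations correlated between monosome and polysome groups with r of 0.161 to 0.422 only. In amino acid starvation polysomes 0, 13.6 and 57.6% of 2-, 4- and 8-fold changes were called without the block and 10.3, 92.4 and 98.5% with it, where 10 of 143 calls were false. In amino acid starvation monosomes 0, 0 and 25.8% were called without and 7.35, 53 and 84.8% with the block (6 of 102 false). For monosome against polysome over 3 conditions the values were 2.94, 84.8 and 87.9%, and 58.8, 92.4 and 97% (13 of 178 false). In serum starvation polysomes they were 0, 9.09 and 63.6%, and 22.1, 89.4 and 100% (4 of 144 false). Without the block 0 calls were false. Of 20 lists 0 were called, where no list was changed as a whole but the 200 changed genes, drawn at random, could be members. Genes were simulated independently of each other, so this does not test lists whose members vary together. Scripts were written in R and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.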

Results

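HEK293 cells, a human embryonic kidney line, were grown in log phase, starved of serum for 2 h or starved of amino acids for 1 h. Ribosome footprints were sequenced from pooled monosome fractions (mRNAs with 1 bound ribosome) and pooled polysome fractions (several). Each of the 6 groups has 2 libraries, A and B. No label says that these are separate cultures, so every p below measures spread between these libraries only. Over 4765 coding genes the first principal component (44.6% of the variance) parts the fractions and the second (19.2%) parts A from B. Most starvation effects are therefore given with a replicate block, a model term for the letter, beside the counts without it. Footprints per gene follow mRNA level and translation alike, and no mRNA libraries were analysed here. Each library was scaled to its own coding footprints, so rises and falls are relative to the other genes of that fraction. A change of all genes together, such as a general loss of polysomes, would not be seen.

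Over the 3 conditions, 1849 of 4765 genes differed between monosomes and polysomes, 811 higher and 1038 lower in monosomes (edgeR quasi-likelihood test, adjusted p under 0.05). With the block 2585 differed, 1141 higher and 1444 lower. Gene values in this paragraph are log2 monosome over polysome without the block. Several of the genes farthest toward monosomes encode short proteins, among them RPL41 (6.23, SE 0.457, adjusted p = 1.05e-06), a ribosomal protein with a called open reading frame (ORF) of 69 nt, OST4 (5.84, SE 0.525, adjusted p = 2.57e-06), of the oligosaccharyltransferase that glycosylates secreted proteins, and ATP5F1E (5.47, SE 0.564, adjusted p = 8.77e-06), of the mitochondrial ATP synthase. BOLA3 (5.69, adjusted p = 1.7e-06), of iron-sulfur cluster assembly, and GPX4 (4.85, adjusted p = 1.15e-06), the selenoprotein that reduces lipid peroxides, lay on the same side. Mitochondrial ribosomal proteins split, with 7 of 65 higher, such as MRPL33 (3.57), and 26 lower in monosomes, such as MRPL13 (-2.19) and MRPS23 (-2.30) (8 and 28 adjusted over the list alone). The list median was -0.62 (camera, adjusted p = 0.0536). Longer ORFs higher in monosomes were those of PABPC1 (3.70, adjusted p = 0.000215), the poly(A)-binding protein, and ATF4 (2.10, SE 0.367, adjusted p = 0.000633), the transcription factor of the integrated stress response. The elongation factors EEF1A1 (1.16, adjusted p = 0.0164) and EEF2 (2.00, adjusted p = 0.0125) were higher too.

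Lower in monosomes were PFDN6 (-2.72, SE 0.34, adjusted p = 4.55e-05), a prefoldin subunit that helps fold actin and tubulin, and PRDX1 (-2.65, SE 0.399, adjusted p = 0.000201), a peroxide-reducing enzyme. The glycolytic enzymes TPI1 (-2.28, adjusted p = 0.000233), PGAM1 (-1.59, adjusted p = 0.000681) and LDHA (-1.26, adjusted p = 0.0136) were lower as well. MYC (0.41, adjusted p = 0.338), RPL3 (-0.25, adjusted p = 0.515) and RPS6 (-0.28, adjusted p = 0.507) did not pass. The proteasome, the protease that degrades ubiquitin-tagged proteins, was the only list of 20 to pass over the 3 conditions. Of its 32 tested genes 15 were lower in monosomes (19 adjusted over the list alone) and 1 higher, with a median of -1.05 (camera, adjusted p = 0.00209, and adjusted p = 0.92 with an estimated correlation). Core subunits such as PSMB2 (-2.62, SE 0.292, adjusted p = 1.84e-05), PSMB5 (-2.38, SE 0.316, adjusted p = 7.28e-05) and PSMB3 (-2.15, SE 0.321, adjusted p = 0.000188) were among them. Initiation factors split, 13 of 43 lower and 8 higher (14 and 8 adjusted over the list alone), with EIF2S2 (-1.78, adjusted p = 0.000225) and EIF1AX (-1.83, adjusted p = 0.000481), which help place the initiator tRNA, lower. Cytosolic ribosomal proteins also split, 12 of 69 higher and 5 lower (11 and 4 adjusted over the list alone). RPS28 (3.31, adjusted p = 0.000109), RPS12 (2.97, adjusted p = 0.000327) and RPS21 (2.86, adjusted p = 0.000248) were among the higher. Other 5'TOP mRNAs start with a pyrimidine tract that ties their translation to growth signals. Of 24, 10 were higher in monosomes, such as TPT1 (1.49, adjusted p = 0.00155), and 0 lower, with a median of 0.63 (camera, adjusted p = 0.0536).

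Within single conditions, 541 genes differed between fractions in log phase, 326 in serum starvation and 339 in amino acid starvation, and 1639, 1355 and 1385 with the block. The counts without the block moved widely when a single library was left out, as given in the part on processing. RPL41 was higher in monosomes in each (6.84, 6.41 and 5.42, adjusted p = 0.000366, 0.000854 and 0.00216). The dehydrogenase HSD17B10 (-3.05, adjusted p = 0.00606), a mitochondrial enzyme, was lower in serum starvation. Proteasome medians were -0.82, -0.90 and -1.02 in log phase, serum and amino acid starvation, with 7, 7 and 2 of 32 genes lower (8, 8 and 2 adjusted over the list alone). Camera gave adjusted p = 0.0242, 0.00134 and 8.98e-05, and adjusted p = 0.887, 0.833 and 0.859 with an estimated correlation. The log phase median was 0.19 without the log phase polysome B library, and the serum median 0.04 without the serum starvation polysome B library. Without any 1 of the 4 starvation polysome libraries the log phase list did not pass (camera, adjusted p = 0.0532 to 0.0585). C2H2 zinc finger genes, DNA-binding proteins that include the KRAB repressors, had 58 of 70 members higher in serum starvation monosomes, 2 of them past the threshold (2 adjusted over the list alone), with a median of 1.08 (camera, adjusted p = 0.000198, and adjusted p = 0.833 with an estimated correlation). That median was -0.57 without the serum starvation monosome B library. RLE scaling raised the median of all genes by 0.203 in log phase, 0.18 in serum starvation and 0.139 over the 3 conditions. Library-size scaling raised it by 0.133 and 0.11 in the first 2 and shifted it by -0.198 in amino acid starvation.

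Proteins of the mitochondrial chromosome are made on mitochondrial ribosomes, and their footprints took a far larger share of the monosome than of the polysome libraries. The 207 ORFs there held 6.95 ± 2.48% of footprints in the 6 monosome libraries (mean ± SD) and 0.193 ± 0.116% in the 6 polysome libraries, a ratio of 36.0. An exact permutation of the fraction labels within condition gave a two-sided p = 0.00926, the smallest it can give. Swaps within the pairs of 1 condition and letter only, chosen after the data were seen, gave an exact p = 0.0312, again the smallest possible. Of the 207 ORFs 186 lay inside protein genes (6.86 and 0.186%). Another 20 lay inside tRNA genes, and their share was higher in monosomes too (0.0831 and 0.00720%, exact permutation within condition, p = 0.00926). The gap is therefore not particular to protein genes. By the permutation within condition 12 of the 13 protein genes reached an exact p = 0.00926 (adjusted p = 0.01), among them ATP6 (1.66% in monosomes, 0.00779% in polysomes), COX1 (1.57 and 0.0731%) and COX2 (1.41 and 0.0239%). ND6, on the other strand from the rest, held 0.0610 and 0.0210% (exact permutation, p = 0.157, and p = 0.0312 by swaps within letter pairs). This measure was chosen after the data were seen, and strand was ignored when ORFs were assigned to these genes.

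Coding ORFs took 34.8 ± 10.1% of footprints in monosome and 61.5 ± 4.39% in polysome libraries (n = 6 each, exact permutation, two-sided p = 0.00926). Annotated coding sequences (8.19 against 15.0%), truncated forms (15.9 against 29.1%) and variants (10.7 against 17.4%) had lower shares in monosomes (exact permutation over 9 ORF types, adjusted p = 0.0208 each). Orphan ORFs had a higher share (4.09 against 1.37%, exact permutation, adjusted p = 0.0208), which was gone without the mitochondrial chromosome (-0.0709 points, exact permutation, adjusted p = 0.806). Swaps of the fraction labels within letter pairs only, an alternative chosen after the data were seen, kept the coding share at an exact p = 0.0312, the smallest possible, but left 0 of the 4 types past the threshold (exact permutation, adjusted p = 0.0703 each), although each difference had the smallest p that these swaps can give. Upstream ORFs (uORFs), in the 5' leader, held 3.59 and 3.41% (exact permutation, adjusted p = 0.927), and iORFs, inside coding sequences, 26.5 and 10.8% (adjusted p = 0.236). ORFs on non-coding RNAs held 23.1 and 16.0% (exact permutation, adjusted p = 0.15). A 9 nt iORF on chromosome 12 alone held 47.9% of log phase monosome library A and 47.5% of amino acid starvation monosome library A, but 0.721 and 0.935% of their B libraries. A 6 nt ORF on a non-coding RNA held 8.72% of amino acid starvation polysome library A and 3.47% of amino acid starvation monosome library A. Leaving out ORFs that take over 5% of a library, both of these among them, was an alternative added after the data were seen. The iORF difference was then 1.86 points (exact permutation, adjusted p = 0.354) and the ncRNA difference 11.3 points (exact permutation, adjusted p = 0.0167). ORFs on non-coding RNAs then held 26.1% in monosomes and 14.8% in polysomes. The coding gap then shrank to 19.6 points, with 42.9% in monosomes and 62.5% in polysomes (exact permutation, p = 0.00926), and annotated coding sequences, truncated forms and variants to -5.26, -9.92 and -4.37 points. Without the log phase or the amino acid starvation polysome A library 0 of the 9 types passed (4 with all libraries, smallest adjusted p = 0.0556 in each case, exact permutation). The differences stayed near their size, with annotated coding sequences at -6.09 and -6.41 points (-6.85 with all libraries) and truncated forms at -12.0 and -13.1 points (-13.2). Among ORFs with a caller p under 1e-4 coding ORFs held 95.9% in monosomes and 95.1% in polysomes (exact permutation, p = 0.0278). That set keeps 13 iORFs, 44 dORFs, 1 orphan ORF, 313 ncRNA ORFs, 49 uORFs and 19 uoORFs. Its coding share is therefore near the ceiling and does not test the difference among all ORFs.

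**Figure D1:**
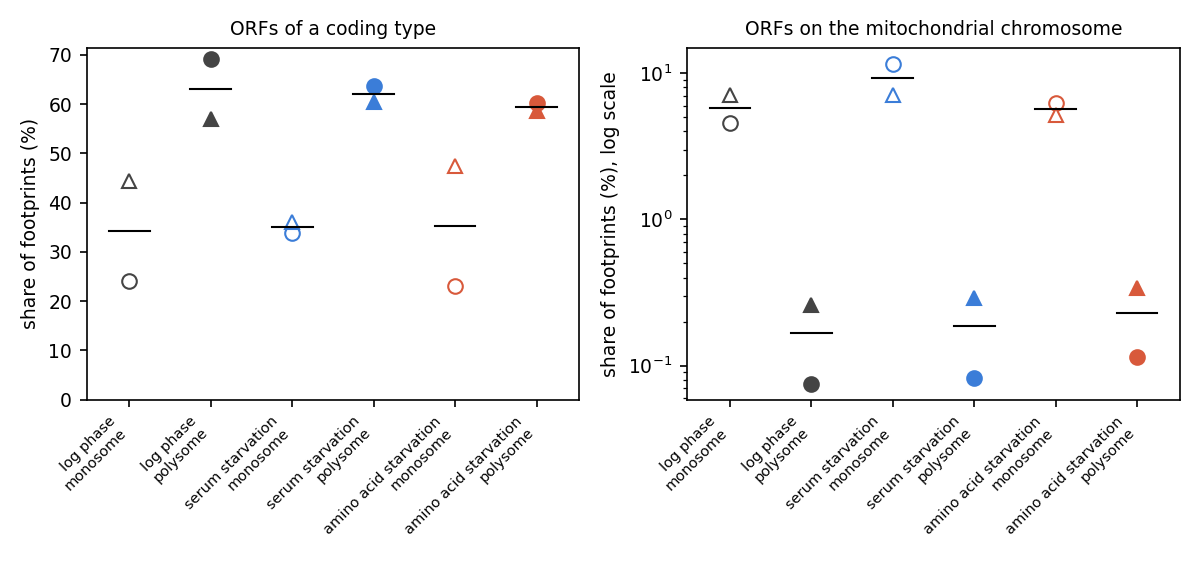
Share of each library's footprints, in percent, on ORFs of a coding type (left) and on ORFs of the mitochondrial chromosome (right, log scale); circles are A libraries, triangles B libraries and bars the mean of the 2. Mitochondrial footprints lie between 4.56 and 11.6% in the monosome libraries and between 0.0753 and 0.340% in the polysome libraries.

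Short called ORFs leaned toward monosomes, but length ordered the genes weakly. Across 4765 genes, which are not independent replicates, Spearman's rho between ORF length and the mean log2 monosome over polysome ratio was -0.12. The A and B pairs gave 0.0289 and -0.177 in log phase, -0.0688 and -0.116 in serum starvation and -0.204 and -0.308 in amino acid starvation. The median ratio was 0.64 for the 908 genes under 300 nt, with 284 higher and 62 lower in monosomes. It was -0.29, -0.55 and -0.12 in the bins from 300, 600 and 1200 nt, and 0.82 for the 247 genes of 2400 nt or more, so the relation was not monotonic. That last bin went both ways between pairs, with a median of -1.84 in the serum starvation A pair against 1.20 in its B pair and 0.26 to 1.24 in the others. RPL41, RPS28 and RPS21 belong to the shortest bin.

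In polysomes of amino acid-starved cells, cytosolic ribosomal protein genes fell relative to the other genes. With the replicate block 53 of 69 fell (62 adjusted over the list alone) and 0 rose, with a median of -2.18 (camera, adjusted p = 7.59e-45, and adjusted p = 0.274 with an estimated correlation). RPL12 (-3.91, SE 0.517, adjusted p = 9.89e-05), RPS27 (-3.62, SE 0.507, adjusted p = 0.000149) and RPL28 (-3.65, SE 0.604, adjusted p = 0.00101) are examples (log2 fold changes), and RPL3 (-1.76, adjusted p = 0.00846) and RPS6 (-1.71, adjusted p = 0.0168) fell less. The family took 12.0 ± 2.89% of coding footprints in log phase and 3.91 ± 0.601% in amino acid starvation polysomes (mean ± SD of 2 libraries). Other 5'TOP mRNAs did not pass as a list: 1 of 24 fell, TPT1 (-1.62, SE 0.414, adjusted p = 0.0138), with a list median of -0.21 (camera, adjusted p = 0.129). Against draws of other genes matched by ORF length, chosen after the data were seen, their median lay low, with 22 of 1000 draws at or below it and a draw median of 0.14. EEF1A1 (-1.21, adjusted p = 0.0801) and EEF2 (-0.30, adjusted p = 0.762) did not pass. Without the block 56 ribosomal protein genes passed adjusted over the list alone, but 0 of 4765 genes passed by edgeR (411 at an unadjusted p under 0.05, 90 by DESeq2). With it 480 passed, 245 higher and 235 lower. Library-size scaling raised the median of all genes by 0.32 in the model without the block. With the block the ribosomal protein median under this scaling was -1.82.

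Across genes, which are not independent replicates, the amino acid starvation change in polysomes rose with ORF length (Spearman's rho 0.355 with the block). In the length bin from 1200 nt 127 genes rose and 1 fell, and in the bin from 300 nt 21 rose and 124 fell. Chaperones, which fold new and damaged proteins, rose in these polysomes relative to the other genes. With the block 14 of 20 rose (17 adjusted over the list alone), with a median of 1.51 (camera, adjusted p = 1.64e-12, and adjusted p = 0.274 with an estimated correlation). DNAJA1 (1.90, SE 0.39, adjusted p = 0.00347), HSP90AB1 (1.83, adjusted p = 0.00756) and CCT8 (2.01, adjusted p = 0.00846) are examples. Of the aminoacyl-tRNA synthetases, which charge tRNAs, 7 of 15 rose (9 adjusted over the list alone, median 1.12), among them RARS1 (1.72, adjusted p = 0.0042). Of the cell cycle genes 8 of 22 rose (15 adjusted over the list alone, median 1.13), such as the replication helicase subunit MCM4 (2.04, adjusted p = 0.00321) and the mitotic cyclin CCNB1 (1.87, adjusted p = 0.0105). Of the SR and hnRNP splicing factors 6 of 29 rose (12 adjusted over the list alone, median 0.92), such as HNRNPM (2.01, adjusted p = 0.00378). Each of these 3 lists had a camera adjusted p = 9.71e-08, and adjusted p = 0.274 with an estimated correlation. In 1000 draws of other genes matched by ORF length, chosen after the data were seen, the highest median was 0.91 for chaperones, 1.13 for synthetases (1 draw reached the list), 0.67 for cell cycle genes and 0.53 for splicing factors. The A and B libraries also differed in this direction. In log phase polysomes A and B chaperones took 0.256 and 0.751% of coding footprints, and splicing factors 0.678 and 1.76%. Ribosomal proteins took 14.0 and 9.91%. In amino acid starvation polysomes A and B these shares were 1.04 and 2.37%, 1.71 and 3.63%, and 4.33 and 3.48%. A difference between preparations along the same axis was not told apart from starvation.

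Ribosome biogenesis factors, which build ribosomes in the nucleolus, also rose in amino acid starvation polysomes, 7 of 21 (10 adjusted over the list alone) with a median of 0.84, such as GNL3 (2.16, adjusted p = 0.00252) and NOLC1 (2.60, adjusted p = 0.00482). Camera gave adjusted p = 1.36e-05, and adjusted p = 0.274 with an estimated correlation. Proteasome genes rose for 5 of 32 (7 adjusted over the list alone), such as PSMD2 (1.77, adjusted p = 0.00756), with a median of 0.71 (camera, adjusted p = 2.99e-05, and adjusted p = 0.291 with an estimated correlation). Length-matched draws reached 0.75 at the highest for ribosome biogenesis and 0.54 for the proteasome. Respiratory chain genes split, 8 of 61 lower and 4 higher (17 and 5 adjusted over the list alone, median -0.73), with UQCRH (-1.77, adjusted p = 0.0111) lower and SDHA (1.58, adjusted p = 0.00793) higher. Camera gave adjusted p = 0.00207, and adjusted p = 0.456 with an estimated correlation. Single genes that rose were the early response transcription factor JUN (2.15, SE 0.386, adjusted p = 0.00152) and the RNA helicase DDX1 (2.38, adjusted p = 0.00203), while EIF4EBP2 (-1.60, adjusted p = 0.00753), a repressor of cap-dependent initiation, fell. Of 18 ATF4 and integrated stress response targets 3 rose (3 adjusted over the list alone): SHMT2 (1.57, adjusted p = 0.0127), of serine metabolism, ATF3 (1.42, adjusted p = 0.0132), a transcription factor, and SLC38A2 (1.22, adjusted p = 0.0385), an amino acid transporter. The list itself did not pass (median 0.32, camera, adjusted p = 0.0589), and 408 of 1000 length-matched draws reached its median. It passed without log phase polysome library A (0.58, adjusted p = 0.0198), serum starvation polysome library A (0.50, adjusted p = 0.0398) or B (0.48, adjusted p = 0.0384), or amino acid starvation polysome library A (0.28, adjusted p = 0.0368). ATF4 (0.15, adjusted p = 0.851) and MYC (1.35, adjusted p = 0.054) did not pass. These single-gene counts depend on the polysome libraries: 1 gene passed without amino acid starvation library A, 7 without B, 8 without log phase library A and 288 without B.

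**Figure D2:**
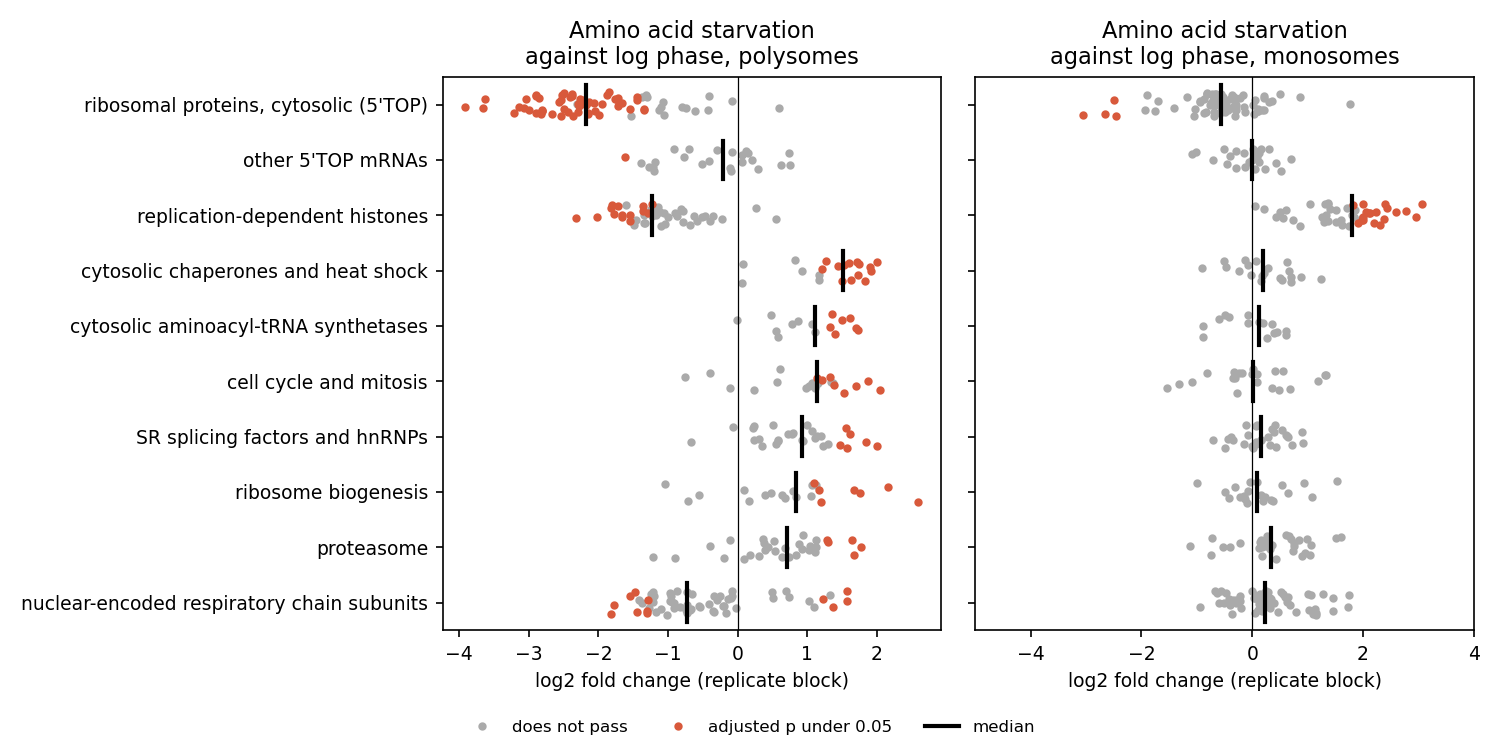
Log2 fold change of each tested gene in amino acid starvation against log phase, with the replicate block, for 10 gene lists in polysomes (left) and monosomes (right); each point is a gene, red where the adjusted p is under 0.05, and black bars are list medians. In polysomes 53 of 69 ribosomal protein genes fell, and in monosomes 19 of 48 histone genes rose.

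Replication-dependent histone mRNAs, which end in a stem-loop instead of a poly(A) tail, fell in polysomes and rose in monosomes of amino acid-starved cells. With the block 14 of 48 fell in polysomes (29 adjusted over the list alone), with a median of -1.23 (camera, adjusted p = 1.64e-12, and adjusted p = 0.291 with an estimated correlation). In monosomes 19 rose (38 adjusted over the list alone), with a median of 1.80 (camera, adjusted p = 3.05e-52, and adjusted p = 0.353 with an estimated correlation). H3C2 (3.07, SE 0.573, adjusted p = 0.00528) and the linker histone H1-1 (2.77, SE 0.504, adjusted p = 0.0044) rose in monosomes, and H4C11 (-2.33, SE 0.438, adjusted p = 0.00203) fell in polysomes. Histone genes include near-identical copies, so the copy a footprint came from is uncertain. The monosome over polysome ratio changed for 55 genes, 51 higher and 4 lower, and 30 of these were histones (43 adjusted over the list alone). All 48 histone values were positive, with a median of 2.93 (camera, adjusted p = 3.19e-70, and adjusted p = 0.199 with an estimated correlation). Histones took 4.53 ± 0.573% of coding footprints in monosomes and 11.6 ± 2.81% in polysomes in log phase, against 12.1 ± 0.424% and 7.21 ± 1.79% in amino acid starvation. Without the block 37 histones passed for the ratio adjusted over the list alone, but 0 of 4765 genes passed by edgeR (202 at an unadjusted p under 0.05, 30 by DESeq2). RLE and library-size scaling shifted the median ratio change of all genes by -0.145 and -0.341 in the model without the block. With the block the histone median under these scalings was 2.78 and 2.57.

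**Figure D3:**
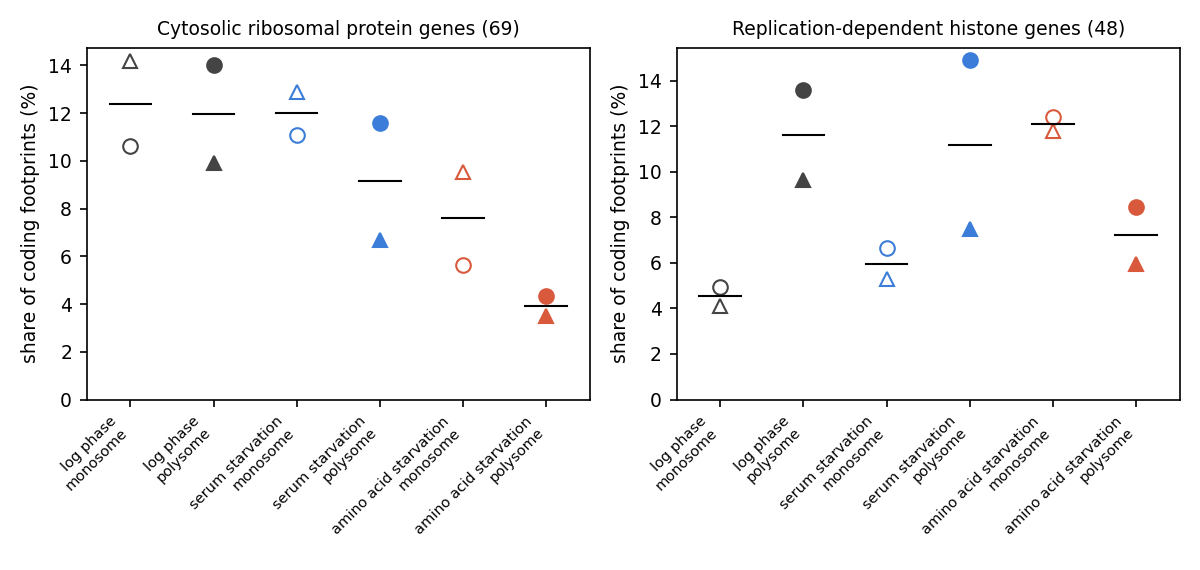
Share of coding footprints, in percent, on the 69 ribosomal protein genes (left) and the 48 histone genes (right) in each library; circles are A libraries, triangles B libraries and bars the mean of the 2. In amino acid starvation the ribosomal protein share of polysomes is 4.33 and 3.48%, and the histone share of monosomes is 12.4 and 11.8%.

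In amino acid starvation monosomes 49 genes changed with the block, 30 higher and 19 lower. Without it 0 passed by edgeR (240 at an unadjusted p under 0.05, about what chance alone would give, and 24 by DESeq2). PMAIP1 (2.38, SE 0.433, adjusted p = 0.0044), which encodes the apoptosis inducer NOXA, rose. Ribosomal protein genes that lie toward monosomes fell: RPL41 (-2.67, adjusted p = 0.0044), RPS12 (-3.06, adjusted p = 0.00662), RPS28 (-2.50, adjusted p = 0.00713) and RPS21 (-2.46, adjusted p = 0.0315). These were 4 of 69 (8 adjusted over the list alone, median -0.57, camera, adjusted p = 1.68e-08, and adjusted p = 0.882 with an estimated correlation), and the list did not pass without amino acid starvation monosome library A (-0.21, camera, adjusted p = 0.139). OST4 (-2.25, adjusted p = 0.0315) fell too. The monosome over polysome ratio of ribosomal protein genes rose, with 64 of 69 higher and a median of 1.63 (camera, adjusted p = 5.78e-21, and adjusted p = 0.353 with an estimated correlation). Of these RPS26 (2.52, adjusted p = 0.0369) and RPL10 (2.48, adjusted p = 0.0396) passed, and 31 adjusted over the list alone. The ratio fell for the autophagy receptor SQSTM1 (-3.43, adjusted p = 0.0108), the splicing factor HNRNPM (-2.40, adjusted p = 0.0447), the CTP synthase CTPS1 (-2.17, adjusted p = 0.036) and the disulfide isomerase PDIA3, which had 0 and 3 footprints in amino acid starvation monosomes, so no size is given. Without either amino acid starvation polysome library 0 genes passed for the ratio, 7 without log phase monosome A, 8 without log phase polysome A and 11 without amino acid starvation monosome B. In monosomes 3 genes passed without amino acid starvation library B and 15 without log phase library B.

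Amino acid and serum starvation were also compared directly. In polysomes 48 genes differed with the block, 2 higher and 46 lower in amino acid starvation, and 0 without it by edgeR (188 at an unadjusted p under 0.05, 37 by DESeq2). Ribosomal protein genes were 28 of the lower (57 adjusted over the list alone), with a median of -1.66 (camera, adjusted p = 2.59e-40, and adjusted p = 0.277 with an estimated correlation), such as RPL28 (-3.35, adjusted p = 0.00502) and RPL12 (-3.28, adjusted p = 0.00166). The count was 0 without either amino acid starvation polysome library, 5 without serum starvation polysome library A and 546 without B. In monosomes 11 genes differed with the block, 10 higher and 1 lower, and 0 without it by edgeR (165 at an unadjusted p under 0.05, 1 by DESeq2). Histones were higher, 3 of 48 (32 adjusted over the list alone), with a median of 1.32 (camera, adjusted p = 5.59e-33, and adjusted p = 0.69 with an estimated correlation), such as H4C1 (2.27, adjusted p = 0.0237).

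Serum starvation against log phase gave few calls. In polysomes 0 of 4765 passed by edgeR with or without the block (47 and 5 at an unadjusted p under 0.05, 0 by DESeq2 either way). The block recovered 22.1% of simulated 2-fold and 89.4% of 4-fold changes, and the model without it 0 and 9.09%. These rates hold for a letter effect shared by both fractions, which the data show only in part. Changes of 2-fold or less are therefore not excluded. Values of 3 gene lists are given first without the block. Ribosomal protein genes were lower in 68 of 69 cases, 0 past the threshold (0 adjusted over the list alone), with a median of -0.39 (camera, adjusted p = 7.83e-19, and adjusted p = 0.527 with an estimated correlation). Chaperones had 17 of 20 higher, with a median of 0.55 (camera, adjusted p = 6.92e-05, and adjusted p = 0.587 with an estimated correlation). Synthetases had 15 of 15 higher, with a median of 0.39 (camera, adjusted p = 0.000317, and adjusted p = 0.587 with an estimated correlation). The serum starvation change in polysomes also rose with ORF length (Spearman's rho 0.288 with the block, genes not being independent replicates). With the block the 3 medians were -0.40, 0.48 and 0.34, and in 1000 length-matched draws, chosen after the data were seen, 0 reached the ribosomal proteins or chaperones and 10 the synthetases. Without serum starvation polysome library B none of these 3 lists passed with the block (-0.02, 0.01 and -0.03, camera, adjusted p = 0.851, 0.503 and 0.796). Chaperones and synthetases also did not pass without log phase polysome library A (0.35 and 0.23, adjusted p = 0.266 and 0.283). The genes with the smallest p did not pass: PNRC1 (1.71, adjusted p = 1), a nuclear receptor coactivator, FTL (1.21, adjusted p = 1), the ferritin light chain, and ID3 (-1.19, adjusted p = 1), an inhibitor of differentiation. MYC (1.00, adjusted p = 1) and ATF4 (-0.83, adjusted p = 1) did not pass either.

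In serum starvation monosomes 0 genes passed without the block by edgeR (84 at an unadjusted p under 0.05, 0 by DESeq2). With it 1 passed, CCDC120, a centrosome protein with 1 and 6 footprints in log phase monosomes and 0 and 139 in serum starvation monosomes, so it rests on library B. Histones had 40 of 48 higher, 0 past the threshold (0 adjusted over the list alone), with a median of 0.51 (camera, adjusted p = 2.05e-05, and adjusted p = 0.877 with an estimated correlation). The change of the monosome over polysome ratio passed for 0 genes without the block by edgeR (39 at an unadjusted p under 0.05, 0 by DESeq2) and for 1 with it, EML6, a microtubule-binding protein with 0 and 6 footprints in serum starvation monosomes. The histone ratio was higher for 41 of 48, with a median of 0.54 (camera, adjusted p = 3.53e-06, and adjusted p = 0.919 with an estimated correlation). With the block it did not pass without serum starvation polysome library B (0.25, camera, adjusted p = 0.312).

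Upstream ORFs were lower in amino acid-starved monosomes, as a class. Class values here are without the replicate block unless said otherwise. The 2099 tested uORFs had a median of -0.66 against log phase and the 1582 that overlap the coding start (uoORFs) a median of -0.55. Camera gave adjusted p = 7.44e-06 and 4.91e-06, and adjusted p = 0.0487 for both with an estimated correlation. With the replicate block as well, neither passed with an estimated correlation (adjusted p = 0.104 and 0.142), and 0 single uORFs or uoORFs passed by edgeR in either model. ORFs downstream of coding sequences (dORFs) had a median of 0.04 (camera, adjusted p = 0.314). Of 10272 kept uORFs 49 had a caller p under 1e-4 (median caller p 0.434), and of 3385 kept uoORFs 19 (median 0.555). Most members of both classes therefore have little support from the caller, and a change on translated upstream ORFs is not shown. Without log phase monosome library B the uORF median was -0.08 and without A -0.69. In polysomes the medians were -0.34 and -0.37 (camera, adjusted p = 0.00936 and 0.000177, and adjusted p = 0.33 and 0.145 with an estimated correlation), and -0.03 and -0.16 without log phase polysome library B (adjusted p = 0.252 and 0.0501). With the block 18 uORFs fell and 2 rose in polysomes, and 36 uoORFs fell and 0 rose. The uoORF of ATF4, a known brake on its coding sequence, had a monosome over polysome log2 ratio of 0.95 (adjusted p = 0.137), and 1.14 with the block (adjusted p = 0.00685). In serum starvation monosomes the uORF median was -0.52 (camera, adjusted p = 4.38e-06, and adjusted p = 0.0432 with an estimated correlation), against the same log phase libraries, so the 2 falls are not independent.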

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

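In this part the length-matched draws and the summed histone footprints were chosen after the result was seen. The scaling test was written before, and the thinned counts and the use of the replicate block in it were added after the data were seen.

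The change of the monosome over polysome ratio between conditions was tested gene by gene, and is given a closer look because the test called genes. With the replicate block 55 passed in amino acid starvation and 1 in serum starvation, EML6, which has 0 and 6 footprints in serum starvation monosomes. By camera 9 of 20 gene lists passed in amino acid starvation and 4 in serum starvation, and none of them passed with an estimated correlation (smallest adjusted p = 0.199 and 0.485). Without serum starvation polysome library B the serum starvation change did not pass for histones (median 0.247) or ribosomal proteins (median 0.0853). For ribosomal proteins it also did not pass without log phase monosome library A (0.226) or log phase polysome library A (0.0757). Without either amino acid starvation polysome library 0 genes passed by edgeR, 7 without log phase monosome A, 8 without log phase polysome A and 11 without amino acid starvation monosome B. Whether the 2 starvations differ from each other in this ratio was not tested.

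Histones make up most of the 55 genes, with a median ratio change of 2.93. Draws of other genes matched by the length of the called ORF reached at most 0.9 in 1000 draws, which argues against that length. Many called ORFs are fragments, so the length of the whole coding sequence was not matched and stays open. Under RLE, library-size scaling and thinning the median was 2.78, 2.57 and 2.89, which argues against depth or scaling. Footprints shared between copies leave the family's sum as it is, and the monosome over polysome ratio of the summed TMM-scaled footprints changed by 2.6 in letter A and 2.32 in letter B (log2). A candidate explanation is a move of histone mRNAs from polysomes to monosomes within 1 h, but a change in mRNA level, in the cell cycle or between the preparations was not tested.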

How the results depend on the processing

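The fraction-specific replicate block, thinning, swaps within letter pairs, leaving out ORFs that take over 5% of a library, sums over all coding ORFs with shared codons repeated, the estimated correlation for ORF classes, the length correlation of blocked ratios, and the alternatives applied together with the replicate block were chosen after the data were seen. So were library-size scaling, no filter, the condition-by-replicate block and CDS-type ORFs alone where they are applied to single gene lists. The other alternatives were chosen before. Numbers are genes that passed unless said otherwise, and the cause of a changed count was not tested. Between monosomes and polysomes in log phase 541 genes passed; the replicate block gave 1639, the condition-by-replicate block 1328, the fraction-specific replicate block 2221, CDS-type ORFs alone 167, thinned counts 360 and DESeq2 823. For serum starvation (326) the same settings gave 1355, 1031, 1931 and 106, DESeq2 623 and the compared groups alone 143. For amino acid starvation (339) they gave 1385, 1079, 1974 and 135, DESeq2 648 and the compared groups alone 763. Over the 3 conditions (1849) CDS-type ORFs alone gave 439, the fraction-specific replicate block 2900 and thinned counts 1173, and with the replicate block (2585) CDS-type ORFs alone gave 586 and thinned counts 1590.

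By the edgeR model of all libraries without a replicate block each starvation contrast had 0 genes. In amino acid starvation polysomes the replicate block gave 480, the fraction-specific replicate block 1414 and DESeq2 90, in monosomes 49, 321 and 24, with 130 for the compared groups alone. Amino acid against serum starvation gave 48, 934 and 37 in polysomes and 11, 121 and 1 in monosomes. Serum starvation gave 3 in polysomes with the fraction-specific replicate block, and 1 and 43 in monosomes with the replicate block and the fraction-specific replicate block. The change of the ratio in amino acid starvation gave 55, 34 with the condition-by-replicate block, 493 with the fraction-specific replicate block and 30 by DESeq2, and in serum starvation 1, 1 and 13 by the 3 replicate blocks. With the replicate block kept, amino acid starvation polysomes gave 134 for CDS-type ORFs alone and 206 for thinned counts, monosomes 26, 81 and, by DESeq2, 176. Amino acid against serum starvation in polysomes gave 11 by library size and 184 by DESeq2, and the ratio change in amino acid starvation 36 by library size, 9 for CDS-type ORFs alone and 170 by DESeq2.

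Of the gene list tests, 73 over 12 contrasts, 0 passed with an estimated correlation, and of 53 ORF class tests 4 did, and 0 among ORFs with a caller p under 1e-4. That set also left 0 of the 4 ORF types whose share differed, and the coding share was 0.8211 points higher in monosomes, near its ceiling in both fractions (95.9 and 95.1%), since few ORFs of other types are in that set. Without ORFs that take over 5% of a library the coding difference went from -26.7 to -19.6 points. Swaps of the fraction labels within letter pairs left 0 of the 4 types as well (exact permutation, adjusted p = 0.0703 each) and kept the coding share (exact permutation, p = 0.0312). Each of the 4 types had the smallest p these swaps can give, so this adjusted p does not speak against their differences. Among named genes that passed, 1082 comparisons with other settings gave the same call and 138 a weaker one; among lists and classes 286 were the same, 64 weaker, 3 stronger and 1 reversed.

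Where a library is left out of its group, the lone library is assumed to vary like the other groups. Leaving out each library in turn gave 92 to 787 genes in log phase (92 and 168 without log phase monosome A and B, 316 without log phase polysome B), 69 to 436 in serum starvation (69 and 73 without its monosome A and B) and 0 to 603 in amino acid starvation (0 without its polysome B, 60 and 66 without its monosome A and B). Over the 3 conditions it gave 1408 to 1884, and 2087 to 2552 with the replicate block. Without a block the ranges were 0 to 26 in amino acid starvation polysomes (26 without serum starvation polysome A), 0 to 15 for amino acid against serum starvation in polysomes, and 0 to 0 for the other starvation contrasts and both ratio changes. With the replicate block they were 1 to 786 in amino acid starvation polysomes (1 and 7 without its A and B, 8 without log phase polysome A), 3 to 134 in monosomes (3 without its B), 0 to 546 for amino acid against serum starvation in polysomes and 0 to 146 for the ratio change (0 in both without either amino acid starvation polysome library). Gene list tests ranged from 63 to 94, ORF class tests from 47 to 58, ORF types from 0 to 5 and the length correlation from -0.233 to -0.0397. Reversed without 1 library were the log2 values of the proteasome in log phase (-1.22 without polysome A to 0.185 without polysome B) and in serum starvation (-1.47 without polysome A to 0.0377 without polysome B), C2H2 zinc finger genes in serum starvation (-0.571 without monosome B to 1.49 without polysome A) and synthetases in serum starvation polysomes (-0.0278 without B to 0.716 without A). For CCDC120 in serum starvation monosomes the fitted values (-5.905 without B to 4.713 without A) are no sizes, since library A holds 0 of its footprints, and the sign without B says nothing. Of the named genes 1467 comparisons gave the same call, 331 a weaker one and 1 a reversed one, and of lists and classes 516, 28 and 4, with 4 stronger.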

Other observations

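Within amino acid starvation, ribosomal protein genes lay toward monosomes, 62 of 69 with a positive log2 ratio and 9 past the threshold (10 adjusted over the list alone), with a median of 1.01 (camera, adjusted p = 1.22e-06, and adjusted p = 0.859 with an estimated correlation). Glycolysis, with a median of -1.12 and 0 of 10 genes positive (camera, adjusted p = 0.0344, and adjusted p = 0.859 with an estimated correlation), and SR and hnRNP splicing factors, with a median of -1.10 (adjusted p = 0.00161, and adjusted p = 0.859 with an estimated correlation), lay toward polysomes. The splicing factors did not pass without amino acid starvation polysome library B (-0.43, adjusted p = 0.168).

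Of the tests in this part, the length-matched draws, the letters taken alone, the comparison with other 5'TOP mRNAs, the background test and the tests without 1 log phase monosome library were chosen after the result was seen, as was the use of the replicate block with other scalings. The ribosomal protein fall in amino acid starvation polysomes had a median of -2.18. Draws of other genes matched by ORF length reached -0.56 at the lowest, with a draw median of -0.26. The median nearest 0 under other scalings was -1.82 (library size), and the letters alone gave -2.4 and -1.8. A fall of this size shared by 5'TOP mRNAs is argued against by the median of the 24 others, -0.205 (SD 0.71). A smaller fall of theirs stays open, since only 22 of 1000 length-matched draws lay at or below that median. Lower ribosomal protein mRNA levels, lower translation of these mRNAs alone or a difference between the preparations may explain the fall, and none of these was tested.

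The uORF fall in amino acid starvation monosomes held among ORFs with at least 50 counts in 2 libraries (-0.574 for uORFs and -0.541 for uoORFs). That filter takes libraries of either fraction, and the polysome libraries are deeper. ORFs with few monosome footprints can therefore pass it, so it does not decide whether low monosome counts matter. Set against the coding change of the same gene the medians were -0.75 and -0.64, with 72.9 and 76.1% of ORFs below 0. A fall of all footprints outside coding ORFs, as a higher background in log phase would give, stays open. Set against coding in the same way the medians were 0.08 for dORFs and -0.07 for iORFs, so neither class showed a fall of that size as a whole. Single ORFs went both ways (SD 1.93 and 1.99). How far these medians vary between libraries was not tested, so they do not settle the question. Without log phase monosome library B the uORF median was -0.0775, so that library could be the source of the uORF fall. Without 1 or the other of the log phase monosome libraries the uoORF medians were -0.511 and -0.753, which argues against such a source there. Fewer ribosomes starting in 5' leaders also stays open as an explanation for uoORFs and was not tested. Of 3385 kept uoORFs 19 had a caller p under 1e-4, so the caller gives most of them little support.

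For the count of 1849 genes between monosomes and polysomes over 3 conditions, 1 of 100 splits of the libraries within condition, the real one, gave as many. The highest other split gave 661, 7 other splits gave more than 0 and the split of A against B gave 0. The real split thus came first, the best rank that 100 splits can give. Splits that mix the fractions put the difference between fractions into the spread, so low counts were likely beforehand. The splits also took no account of the letters, so they do not exclude chance.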
